A study of Mus musculus with 4 samples.

How the data were processed

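Spatial gene expression was measured with the 10x Genomics Visium assay, which captures RNA from a tissue section on an array of barcoded spots, in 4 heart sections of 10 µm from ICR mice. Per the labels' protocols, the apex of the left ventricle was touched with a cooled probe for 5 seconds at postnatal day 1, and fresh frozen hearts were embedded and cut. Hearts were taken 1, 4, 7 and 14 days after this cryoinjury, called d1, d4, d7 and d14 here, so the animals were at postnatal days 2, 5, 8 and 15. Each time point had 1 section, no section of an uninjured heart is labelled, and per the series design the hearts were cut until the injured area could be seen.

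The deposited values were raw UMI counts per gene and spot, made with Space Ranger 1.3.0 per the file headers, on genome build mm10 per the submitters' processing notes. Those notes also name Seurat 4.1.1 without stating its role. The rule by which the listed spots were selected upstream is not stated. Spot positions and images were not used here, so a region is a set of spots with similar expression and not a mapped place. The matrices held 32285 features, of which 32235 were matched by Ensembl ID to GENCODE vM21 (GRCm38), and 38 symbols were shared by several IDs and were kept apart by ID.

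Spots with at least 500 UMIs were kept. Counts were summed over the spots of a section or region and divided by the total without 8 haemoglobin and 13 mitochondrially encoded genes, giving CPM (UMIs per 1e6 UMIs). Ratios carried an exact conditional binomial (Clopper-Pearson) 95% interval, CPM values an exact Poisson interval and shares of spots an exact Clopper-Pearson interval. These intervals cover counting error only. With 1 section per time point no test between time points was possible and no p-value is given for one. Spots of a section are neighbours in 1 heart and were not treated as replicates.

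Each of d4, d7 and d14 was compared with d1. A gene was counted as at least 2-fold higher or lower when it reached 20 CPM in 1 of the compared sections, its ratio was at least 2 or at most 0.5, and its interval excluded 1. For each of 29 gene lists, the median log2 ratio over members with at least 10 UMIs was given with an order-statistic 95% interval over members, and with its percentile among 10000 random lists matched on size and mean expression. Members at 0 UMIs in 1 section entered at a floor of 3 counts per section. The lists were immediate early, senescence arrest, senescence secretory, proliferation, hypoxia, agrin and Yap, interferon response, immature and mature cardiomyocyte, fatty acid oxidation, glycolysis, imprinted growth, endothelial, mural, respiratory chain, matrix, fibroblast, macrophage, neutrophil, lymphocyte, epicardial, atrial, red blood cell, adipocyte, skeletal muscle, lung epithelium, Schwann, reference and injury region. Aldoa, whose symbol several IDs share, was not measured in the glycolysis list.

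The spots of each section were clustered separately in scanpy 1.11.5 with Leiden (igraph 0.11.9, resolution 0.8) on 15 principal components and 15 neighbours of 2000 variable genes, after log transformation of counts per 10000. The 252 genes of the first 14 lists named above, the outcome lists, were left out of the clustering. The injury-list-rich region was the cluster of at least 10 spots with the largest share of UMIs from the injury region list, which holds matrix, macrophage and neutrophil genes such as Fn1, Tnc, Postn, Lgals3 and S100a8. Genes of that list define the region and are not results. The region was compared with all other spots of its section for genes with at least 20 UMIs, with the same rule of size. Across spots, Spearman's rho between Egr1 and the share of UMIs of a list was computed after thinning each spot to 2500 UMIs, and set against 1000 matched random lists.

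The genes named over time were the 10 with the largest and the 10 with the smallest ratio among counted genes reaching 50 CPM, without predicted, ribosomal protein, haemoglobin, mitochondrially encoded, Xist, Tsix and Y-linked genes. In the region they were drawn from outcome list members past the rule of size. Egr1, Cdkn1a and Agrn were named in every comparison, and up to 4 members of each list with the most UMIs could be. Which of these members, and which others, were given as examples was chosen after their values were seen. These rules, the gene lists, the settings and the alternatives were fixed before the data were examined, except 1 added alternative, a region without spots holding a skeletal muscle UMI.

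The alternatives were CPM over all genes, TMM scaling (edgeR 4.0.16, R 4.3.3), all spots, spots with at least 1500 UMIs, means over spots, leaving out the region or the cluster with the largest atrial share, other gene minimums, Leiden resolutions of 0.5 and 1.2, joint clustering, the top 10% of spots by the injury list, the matrix or macrophage list in place of the injury region list, and rho without thinning or outside the region. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

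The steps were tested on simulated data drawn from the real means and depths. For d4 against d1 (6529 genes run), 100% of 50 genes planted at 3-fold were called, 84% at 0.3333-fold, 0% at 1.5-fold and 0% at 0.6667-fold. For d7 against d1 (6571 genes run) these shares were 100%, 98%, 0% and 0%, and for d14 against d1 (6577 genes run) 100%, 98%, 0% and 2%. None of the 6340, 6375 and 6380 unchanged genes was called, and their intervals held the true ratio in 95.1%, 95.2% and 95.2% of cases. Both simulated sections were Poisson counts from the d1 means, so these shares cover counting error and no variation between hearts. In simulated sections of 32285 genes, all planted region spots were found (35 at d1, 53 at d4, 55 at d7, 142 at d14). Egr1, planted there at 2.84, 2.77, 2.69 and 2.81-fold, was estimated at 2.44, 2.57, 2.61 and 2.88-fold. At d1 the interval of 0.82 to 6.03 included 1. The planted spots carried the real region's profile outside the outcome lists, so their recovery was likely in advance. Of 200 random lists of 15 genes in the d4 against d1 comparison (13168 genes run), 10% lay outside the 5th to 95th percentile.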

Results

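Visium spots were sequenced from 4 cryoinjured neonatal mouse hearts, 1 section at each of 1, 4, 7 and 14 days after injury at postnatal day 1. The 445 spots kept at d1 had a median of 7810 UMIs, the 662 at d4 had 7998, the 774 at d7 had 8028 and the 1175 at d14 had 3770. The total UMIs in the matrices were 3419864, 6187656, 6358894 and 4741982 in that order. Mitochondrially encoded genes took 5.57% of UMIs at d1, 5.17% at d4, 11.6% at d7 and 8.54% at d14. Xist, which is expressed from the inactive X chromosome of female cells, had 199 UMIs at d1, 341 at d4, 1 at d7 and 158 at d14. The Y-linked gene Eif2s3y had 460 UMIs at d7 and 0 in the other sections. The d7 section therefore differed from the others in these sex-linked genes as well as in time. Time after injury ran together with postnatal age in all comparisons between sections, and no difference has a replicate check.

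Egr1, an immediate early zinc finger transcription factor named in the series title, was higher at d4 and d7 than at d1 and d14. It lies on chromosome 18 from 34859823 to 34864984 in GRCm38 (ENSMUSG00000038418). Its level over whole sections was 15.2 CPM at d1 (95% interval 11.2 to 20.1, 49 UMIs), 66 at d4 (59.6 to 73.0, 386 UMIs), 70.4 at d7 (63.6 to 77.7, 392 UMIs) and 12.5 at d14 (9.42 to 16.4, 54 UMIs). Against d1 this was 4.34-fold (3.22 to 5.98) at d4, 4.63-fold (3.44 to 6.37) at d7 and 0.826-fold (0.550 to 1.24) at d14. The share of spots with an Egr1 UMI was 9.21%, 36.0%, 37.7% and 3.91% in order of time. After thinning every spot to 2500 UMIs, the shares were 3.21%, 13.2%, 13.7% and 2.87%, with 40, 3, 3 and 131 shallower spots left out.

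Egr1 also differed between groups of spots. It was 7.63-fold higher (3.97 to 14.2) in the injury-list-rich region than in the rest of the section at d1, at 81.0 against 10.6 CPM with 17 UMIs in the region (log2 ratio 2.93, or 2.27 with joint clustering). The ratio was 2.20 (1.71 to 2.82) at d4, where the region had 128 CPM and the rest 58.3. It was 1.07 (0.703 to 1.58) at d7, with 75.1 against 70.1 CPM, and 4.63 (2.56 to 8.22) at d14, with 39.5 against 8.54 CPM. Outside the region, Egr1 was thus 10.6, 58.3, 70.1 and 8.54 CPM in order of time.

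**Figure D1:**
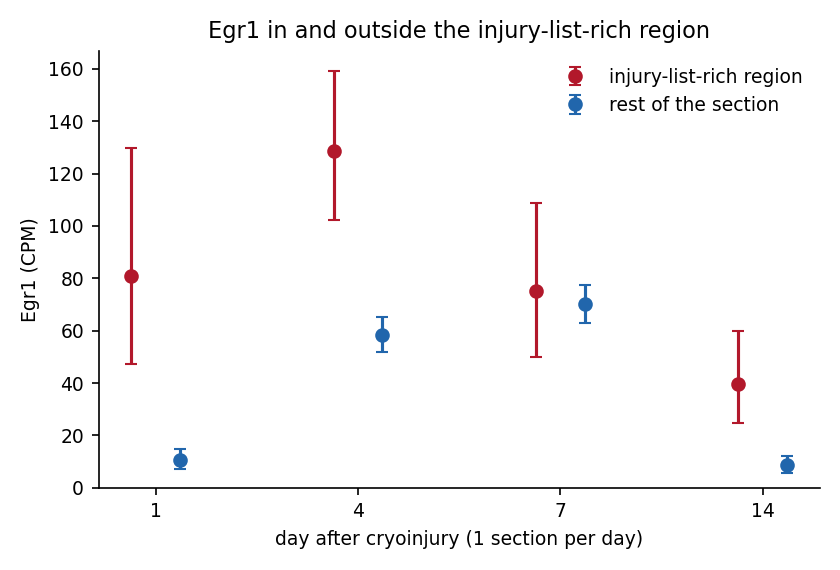
Egr1 level in CPM (vertical axis) by day after cryoinjury, in the injury-list-rich region (red) and in the rest of the section (blue), with exact Poisson 95% intervals that cover counting error only. The rest of the section had 58.3 CPM at d4 and 70.1 CPM at d7, against 10.6 at d1 and 8.54 at d14.

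Cdkn1a, which encodes the cell cycle inhibitor p21 and lies on chromosome 17 from 29090976 to 29100727 (ENSMUSG00000023067), followed the opposite order over time. It had 45.6 CPM at d1, 33.7 at d4, 30.9 at d7 and 92.7 at d14, which against d1 was 0.739-fold (0.594 to 0.922), 0.678-fold (0.540 to 0.850) and 2.03-fold (1.68 to 2.47). In the region it was 2.31-fold higher (1.62 to 3.26) than in the rest at d4 and 1.36-fold (1.03 to 1.77) at d14. Its ratios of 1.16 (0.567 to 2.15) at d1 and 1.43 (0.798 to 2.40) at d7 had intervals that included 1. Agrn, which encodes the extracellular matrix proteoglycan agrin (chromosome 4, 156165290 to 156197488, ENSMUSG00000041936), had 83.1, 127, 98.2 and 97.3 CPM in order of time. It was 1.53-fold higher (1.33 to 1.76) at d4 than at d1, and its ratios of region to rest were 0.973 (0.558 to 1.59) at d1, 1.21 (0.967 to 1.5) at d4, 1.98 (1.51 to 2.56) at d7 and 1.305 (0.991 to 1.70) at d14.

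The comparison of d4 with d1 asks how the heart differed 4 days after injury from the day after it. Genes of dividing cells and of extracellular matrix were higher at d4, while 5 of 19 macrophage genes, 2 of 8 neutrophil genes, 3 of 24 fatty acid oxidation genes and 2 of 19 glycolysis genes were lower. All 21 proliferation genes past the rule of size were higher, of 35 measured (median log2 ratio 1.42, interval 1.14 to 1.76). Among them, the mitotic cyclin Ccnb1 went from 10.5 to 53.2 CPM and the proliferation marker Mki67 from 33.8 to 104 CPM. Of 18 matrix genes, 12 were higher and 0 lower (median 1.14), with the matricellular gene Postn at 242 against 1062 CPM and the collagen Col3a1 at 982 against 2390. Without the region in either section the matrix median was 0.74.

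Among the genes with the largest ratios at d4 were Mfap4, an elastic fibre protein (20.5 to 189 CPM), the heparin-binding growth factors Mdk (29.2 to 193) and Ptn (57.1 to 270), the homeobox gene Meox1 (8.68 to 52.7), the fibril-associated collagen Col14a1 (39.4 to 209), the smooth muscle calponin Cnn1 (11.2 to 60.4), Megf6 (18.0 to 120) and AA465934 (7.44 to 120). AA465934 had 6.29 CPM at d7 and 111 at d14, so it did not follow the order of time. With 1 heart per time point, a difference between animals cannot be told from a change after injury. Nppa, the atrial natriuretic peptide gene, was 4.99-fold higher (4.83 to 5.15), at 6751 CPM. Among the genes with the smallest ratios, Serpina3n, an acute-phase protease inhibitor, had 73.8 CPM at d1 and 0.513 at d4, and Spp1, which encodes osteopontin, had 374 and 3.25. The macrophage glycoprotein gene Gpnmb was 23.1-fold lower, the chemokine genes Ccl6 and Ccl2 21.2-fold and 16.8-fold lower, galectin-3 (Lgals3) 10.1-fold lower and the neutrophil gene S100a8 8.07-fold lower. Hif3a (59.5 to 5.13 CPM), the transcription factor Klf15 (51.2 to 8.89) and the metallothionein Mt2 (158 to 28.4) were also among the 10 lowest.

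In all, 341 genes were at least 2-fold higher and 105 lower at d4, of 7276 that reached 20 CPM. The median log2 ratio of all these genes was 0.17, and -0.03 with TMM scaling, so small list medians at d4 include that shift. Matched random lists had d4 medians of up to 0.46 (for the Schwann list). The epicardial median of 0.37 at d4 lay at percentile 62.3 of its random lists, which had a median of 0.31. With TMM scaling the split was 192 higher (56.6% of calls) and 147 lower, in place of 76.5% higher.

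At d7 against d1, fibroblast, matrix and immediate early genes were among those higher (7 of 18 matrix genes), and 4 of 19 macrophage genes, 2 of 7 neutrophil genes, 4 of 19 glycolysis genes and 3 of 11 hypoxia genes were lower. Of 10 fibroblast genes, 6 were higher (median log2 ratio 1.35), with the collagen-binding proteoglycan genes Dcn at 213 against 625 CPM and Lum at 64.8 against 302. Of 21 immediate early genes, 8 were higher, among them the nuclear receptor gene Nr4a1 (8.37 to 109 CPM), Atf3 (4.96 to 28.2), Btg2 (10.9 to 60.2) and Fos (9.30 to 23.0), and Myc was lower (31.6 to 9.34). The list median was 0.86 (0.31 to 1.75). Of 11 imprinted growth genes, 6 were lower and 0 higher (median -1.06), among them H19 at 581 against 219 CPM.

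The largest ratio at d7 was that of Wfdc18, at 61.4 against 0.31 CPM, which rests on 1 UMI at d1 (198-fold, 35.3 to 7844.5). Of its 342 UMIs at d7, 330 came from the 55 spots of the injury-list-rich region, and the rest of the section had 2.31 CPM. Ccl21a (1.55 to 55.1 CPM), a chemokine gene with near-identical copies whose counts are therefore uncertain, the matricellular gene Ccn3 (9.30 to 71.6), the class I histocompatibility gene H2-K1 (41.6 to 287), the muscle ankyrin repeat gene Ankrd23 (47.8 to 293) Islr (9.92 to 55.7), Mfap4 (20.5 to 186) and Mdk (29.2 to 156) were also among the 10 highest. Of the 307 Ccl21a UMIs at d7, 245 also came from the region, and the rest of the section had 11.9 CPM. H2-K1 ranged from 121 CPM in the largest d7 cluster to 2113 in a cluster of 20 spots. Spp1 was 416-fold lower, Serpina3n 68.5-fold, Hif3a 47.4-fold and Fkbp5, a co-chaperone of the glucocorticoid receptor, 11.4-fold. Gpnmb, Lgals3, Ccl6, S100a8, S100a9 and Cstdc5 were 9.50-fold to 36.7-fold lower. In all, 237 genes were at least 2-fold higher and 196 lower, of 6870. With CPM over all genes the split was 192 higher (44.0% of calls) and 244 lower, in place of 54.7% higher, and the median log2 ratio of all genes was -0.14 in place of -0.03. This section also had the highest mitochondrial share, and 6 skeletal muscle genes were measured with a median log2 ratio of 3.16 (-0.73 to 3.86, or 4.29 as means over spots) and none past the rule, among them the fast myosin light chain gene Mylpf (2.17 to 12.7 CPM).

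At d14 against d1, proliferation genes and imprinted growth genes were lower and fibroblast genes were higher. Of 35 proliferation genes, 14 were lower and 0 higher (median log2 ratio -2.47, interval -2.79 to -2.00), with Top2a at 34.7 against 3.25 CPM and Mki67 at 33.8 against 4.88. Tnni1, the slow skeletal troponin I of fetal heart muscle, was 333-fold lower, at 2242 against 6.74 CPM, and the slow myosin gene Myh7 went from 2700 to 347 CPM, while the immature cardiomyocyte list they belong to had a median of 0.00. Of 19 mature cardiomyocyte genes, 5 were higher (median 0.73), among them myoglobin (Mb, 6925 to 17262 CPM) and the mitochondrial creatine kinase Ckmt2 (399 to 2336). Of 10 fibroblast genes, 8 were higher (median 1.98), and of 11 imprinted growth genes 9 were lower (median -1.80), with Igf2 at 507 against 169 CPM and H19 at 581 against 67.1.

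Strit1, whose small peptide promotes calcium uptake by the sarcoplasmic reticulum, was 40.8-fold higher at d14 (23.2 to 79.3), and the fibroblast gene Pi16 35.8-fold (19.8 to 72.1). The class II histocompatibility gene H2-Aa (0.93 to 56.2 CPM, 3 UMIs at d1), Ccl21a (1.55 to 129), the amino acid transporter gene Slc38a3 (2.17 to 55.3), Art1 (8.37 to 157), Csdc2 (3.72 to 56.0), C1qtnf9 (3.72 to 51.6) and Pltp (9.30 to 108) were the others among the 10 highest, with AA465934 (7.44 to 111). Of the 555 Ccl21a UMIs at d14, 410 came from the 142 spots of the injury-list-rich region, and the rest of the section had 38.7 CPM. AA465934 had 6.29 CPM at d7. The lowest after Tnni1 and Spp1 were Ccl2 (29.2-fold), the decarboxylase gene Ddc (29.0-fold), Cited1 (24.98-fold) and Bex1 (23.3-fold). The DNA replication genes Tk1, Cdt1 and Rrm2 were 13.2-fold, 12.7-fold and 12.1-fold lower, and Gng2 12.9-fold. In all, 511 genes were at least 2-fold higher and 424 lower, of 6982. The d14 spots were the shallowest, with a median of 1626 genes detected against 2718 at d1.

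Across the series of sections, proliferation genes had medians of 1.42, 0.52 and -2.47 on the log2 scale at d4, d7 and d14. At d7, 7 of them were higher, all mitotic such as Ccnb1 (26.4 CPM), Cdc20 (30.9) and Plk1, and the replication factor Mcm5 was lower (33.0 against 69.5 CPM). Immature cardiomyocyte genes did not move together. At d4, 4 of 7 were higher (Acta1, Nppa, Ankrd1 and Myl4, median 1.2, or 0.51 as means over spots). At d7, Nppb and Ankrd1 were higher, with Ankrd1 at 1963 against 523 CPM, and Myh7, Tnni1 and Nppa lower (median 0.21, mean -0.13, and -0.58 without the region). At d14, 1 was higher and 3 lower (median 0.00, mean -1.34), and that median was below 0 with CPM over all genes. Mature cardiomyocyte genes had medians of -0.04, 0.22 and 0.73, with the M-band gene Myom2 higher in all 3 comparisons. Fatty acid oxidation genes had medians of -0.49, -0.44 and 0.02, the last -0.04 with CPM over all genes and with a mean of -0.12. Glycolysis genes had medians of -0.39, -0.45 and -0.48, with the glucose transporter gene Slc2a1 and the lactate transporter gene Slc16a3 lower in all 3, and Hk2 higher at d14 (51.2 to 150 CPM). Of 24 respiratory chain genes, 1 was lower at d4 (Cox7b, 5045 to 2313 CPM) and 0 passed the rule at d7 and d14. Their medians were -0.26, -0.00 and 0.05, the d7 value above 0 with TMM scaling and with a mean of 0.02, and the d14 value below 0 with CPM over all genes.

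Of 14 senescence arrest genes, 0 passed the rule of size at d4, 1 was lower at d7 (Gadd45b, 22.9 to 10.2 CPM) and 2 were higher at d14, Cdkn1a and Gadd45a (10.2 to 22.3). The medians were 0.32, 0.03 and 0.26, and the d7 value was -0.08 with CPM over all genes and had a mean of -0.01. They lay at percentiles 80.8, 61.55 and 93.4 of matched random lists, which had a median of 0.21 at d4. Senescence secretory genes split, with 3 higher and 3 lower at d4, 1 and 5 at d7, and 3 and 4 at d14. Spp1 and the chemokine genes Ccl2 and Ccl7 were lower in all 3, and Igfbp7, which encodes a secreted binding protein of insulin-like growth factors, was higher (316, 778, 652 and 1077 CPM in order of time). The secretory medians were -0.24, -0.32 and 0.21 with means of -0.61, -0.61 and -0.33, so median and mean differed in sign at d14. Of the 12 agrin and Yap genes, 1 passed the rule, the receptor tyrosine kinase gene Axl at d14 (58.6 to 169 CPM), with medians of 0.43, -0.04 and 0.25 and a mean of 0.03 at d7. Hypoxia genes had medians of -0.14, -0.75 and 0.29, with the oxygen sensor gene Egln3 lower at d4 (67.9 to 17.1 CPM) and at d7 (26.4). Immediate early genes had medians of 0.61 and 0.32 at d4 and d14, from 0.30 to 0.67 and from 0.07 to 0.38 over the alternatives. Jun and Btg2 were higher in all 3 comparisons and Myc lower in all 3. Interferon response genes had medians of 0.95, 1.01 and 1.48, with Stat2 (7.13 to 20.4 CPM) past the rule at d14.

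Markers of other cell types differed between the sections too. Macrophage genes had medians of -0.66, -0.31 and -0.02, the d14 value above 0 with TMM scaling, and without the region the d7 and d14 values were 0.13 and 0.66. The d4 value was -1.39 without the cluster with the largest atrial share. That cluster was the injury-list-rich region at d4, d7 and d14 but another cluster at d1. Leaving it out therefore took region spots from the later sections only and does not isolate atrial tissue. Arg1 and Lgals3 were lower in all 3 comparisons, while Csf1r was higher in all 3 (12.1, 26.3, 26.8 and 50.2 CPM in order of time) and C1qa higher at d14 (23.6 to 84.1). Neutrophil genes had medians of -2.56, -3.92 and -1.24, the last -1.86 without that cluster, with S100a8 and S100a9 lower in all 3. Endothelial genes had medians of 0.35, 0.31 and 0.59, with Aplnr higher in all 3 (31.0 to 108 CPM at d4), Cldn5 higher at d7 and d14, Tie1 higher at d14, Vwf lower at d4 and d7 (79.1, 38.8 and 23.9 CPM at d1, d4 and d7) and Eng lower at d7. Mural genes had medians of 0.76, 0.38 and 0.95, the d7 value from 0.02 to 0.63 over the alternatives. The pericyte genes Rgs5 and Kcnj8 were higher and the myosin light chain gene Myl9 lower at d7 and d14. Matrix genes had medians of 0.67 at d7 and 0.39 at d14, which were 0.31 and 0.08 without the cluster with the largest atrial share, with Col3a1 and Loxl1 higher and Cthrc1 and Thbs1 lower at d14. Fibroblast genes had a median of 0.97 at d4. Epicardial genes had medians of 0.37, -0.23 and -1.02, which were 1.12, 0.15 and -0.34 over members with 50 or more UMIs, the d7 value also above 0 as means over spots, with Krt18 higher at d4 and Aldh1a2 lower at d14. Atrial genes had medians of -0.07, -1.07 and 0.51 with a mean of -0.84 at d14, the first 2 turning to 0.43 and 0.08 over members with 50 or more UMIs, and the atrial light chain gene Myl7 was lower in all 3 (45.6, 12.8, 1.44 and 1.39 CPM) and Dkk3 higher at d4 and d7. Lymphocyte medians of 2.09, 1.76 and 2.36 (1.39 at d4 as means over spots, 2.42 and 2.995 at d7 and d14 without the cluster with the largest atrial share) and Schwann medians of 1.51, 1.60 and 1.21 rested on 3 to 5 members, none past the rule. Red blood cell medians were 1.48, 2.77 and 2.49. Reference genes had medians of 0.06, -0.02 and -0.14, the first below 0 and the second above 0 with TMM scaling, with Ppia lower at d14 (1515 to 555 CPM). Adipocyte and lung epithelium genes had fewer than 3 measured members.

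**Figure D2:**
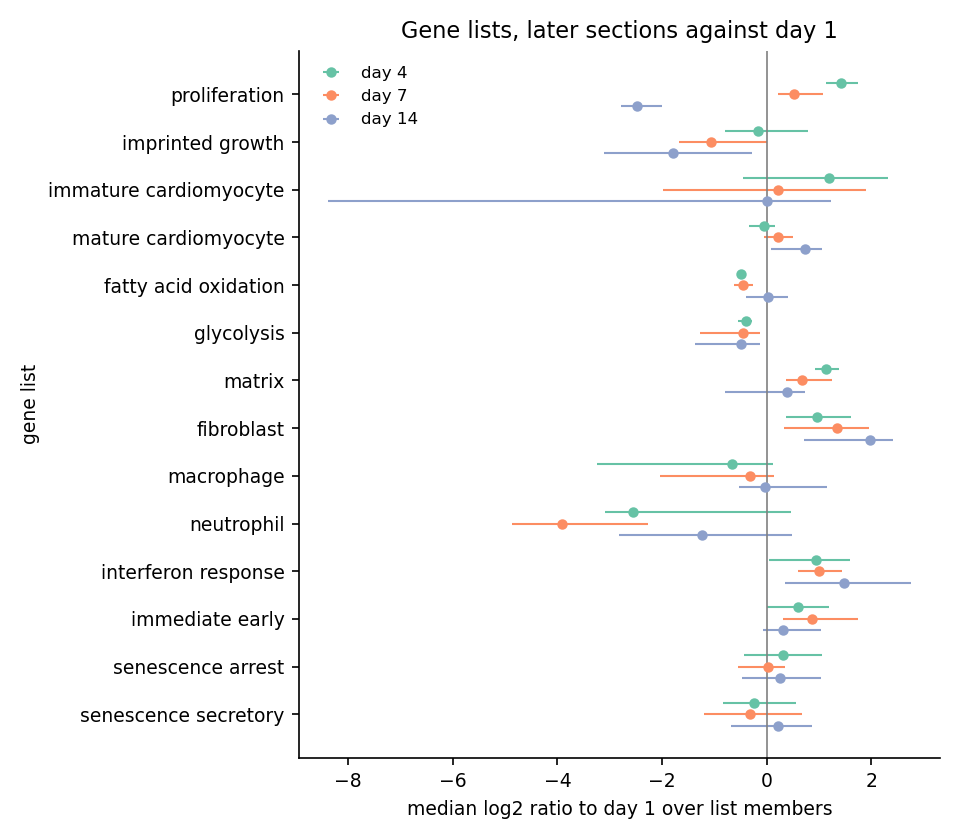
Median log2 ratio of each gene list's members to d1 (horizontal axis) for d4, d7 and d14, with order-statistic 95% intervals over members. Proliferation genes lay at 1.42, 0.52 and -2.47, and fibroblast genes at 0.97, 1.35 and 1.98.

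The injury-list-rich region asks what set the cluster richest in genes of the injury region list apart from the rest of the same section. The regions of different sections were not shown to be the same kind of tissue. At d4, d7 and d14, but not at d1, the region was also the cluster with the largest atrial share. It held 35 spots at d1 (7.87%, 5.54% to 10.8%), 53 at d4 (8.01%), 55 at d7 (7.11%) and 142 at d14 (12.1%). The injury region list took 0.947%, 0.911%, 1.00% and 0.339% of its UMIs, against 0.0929%, 0.159%, 0.136% and 0.0799% in the rest. Its leading genes were Spp1, Il1rn, Gpnmb, Arg1 and Ccl6 at d1, Ccn5, Wfdc18, Tagln, Fmod and Cthrc1 at d4, Wfdc18, Car3, Osr1, C1qtnf3 and Myh3 at d7, and Gpnmb, Mmp12, Cfd, Cilp and C4b at d14. As a description, macrophage genes had region over rest medians of 4.65, 2.90, 2.21 and 1.5, matrix genes 2.17, 2.76, 2.72 and 2.06, and fibroblast genes 0.93, 1.28, 1.52 and 1.23. Respiratory chain genes had -0.84, -1.20, -1.07 and -0.66. The d7 region also held skeletal muscle genes, with Mylpf at 148 CPM against 3.08 in the rest and the embryonic myosin gene Myh3 at 113 against 0.962, and red blood cell genes (median 2.20). The median UMIs per spot in region and rest were 6068 and 7978 at d1, 12769 and 7414 at d4, 7685 and 8042 at d7, and 4070 and 3725 at d14.

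Senescence secretory genes had region over rest medians of 1.64, 1.83, 1.84 and 1.48 at d1, d4, d7 and d14 (interval at d1 -0.10 to 3.78), each at percentile 100 of matched random lists, with 9 of 15, 10 of 16, 10 of 15 and 11 of 17 members higher. Timp1, an inhibitor of metalloproteinases, was 13.7-fold, 4.72-fold, 8.32-fold and 17.1-fold higher in order of time, and Igfbp7 3.71-fold, 5.75-fold, 3.60-fold and 2.80-fold. The chemokine genes Ccl7 and Ccl2 were 58.5-fold and 38.9-fold higher at d1 and Spp1 124-fold (103 to 151). Gdf15 was 5.92-fold higher at d4 and 6.38-fold at d14, and the metalloproteinase gene Mmp12 64.0-fold at d14 (27.7 to 182). The growth factor gene Vegfa was lower at d4 (0.387-fold) and d7 (0.467-fold).

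Senescence arrest genes had lower medians in the region than secretory genes, at 0.59, 0.63, 0.52 and 0.21. These lay at percentiles 88.7, 99.2, 89.2 and 47.2 of matched random lists, with 2 of 9, 4 of 14, 3 of 11 and 1 of 12 members higher. Over the alternatives the d1 median ran from 0.06 to 0.77 and the d7 median from 0.22 to 0.59. Members past the rule were Gadd45g and Glb1, which encodes lysosomal beta-galactosidase, at d1, then Cdkn1a, Gadd45b, Plaur and Trp53inp1 at d4, Gadd45b, Glb1 and Plaur at d7, and Gadd45b at d14. Gadd45b was 2.47-fold, 7.54-fold and 2.12-fold higher at d4, d7 and d14. Plaur, the urokinase receptor gene, was 5.23-fold higher at d4 and 3.14-fold at d7. These genes were measured together with the macrophage, matrix and fibroblast genes above, which were also higher in the region.

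Mature cardiomyocyte genes had region medians of -0.95, -1.74, -1.34 and -0.64, with 9, 16, 16 and 0 of 19 lower. The calcium pump gene Atp2a2 was at 0.437, 0.180, 0.302 and 0.507 times the rest in order of time, and myoglobin (Mb) at 0.418, 0.234, 0.390 and 0.682. Fatty acid oxidation genes had medians of -1.10, -1.80, -1.25 and -0.80, with 14, 22, 21 and 1 of 24 lower, for example Fabp3 at 0.372, 0.261, 0.377 and 0.648 times the rest. Lower levels of heart muscle genes were likely in advance, because the region was picked by a list holding matrix and macrophage genes. Fewer heart muscle cells per spot and lower levels within these cells cannot be told apart here. Immature cardiomyocyte genes had medians of 1.02, 1.03, -0.02 and 2.04, the d1 value 0.33 with joint clustering, the d7 value above 0 with CPM over all genes and with a mean of 1.01. Skeletal actin (Acta1) was 4.1-fold, 4.79-fold, 4.07-fold and 4.53-fold higher, and Nppa 2.03-fold, 3.47-fold, 12.1-fold and 5.08-fold. Myl4, an atrial and fetal light chain gene that skeletal muscle also expresses, was 12.0-fold higher at d7. Because the d7 region held skeletal muscle genes, the d7 ratios of Acta1 and Myl4 cannot be assigned to heart muscle. Atrial genes had region medians of 1.87, 1.28 and 0.24 at d4, d7 and d14, each with an interval that included 0. Nppa and Myl4 alone therefore do not tell immature from atrial heart muscle. Tnni1 was at 0.177 times the rest at d4, 0.5 at d7 and 4.12 at d14, and Myh7 at 0.413 at d4.

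Immediate early genes had region medians of 1.11 at d1 (8 of 14 higher), 0.62 at d4 (interval -0.17 to 1.18, 7 of 18) and 0.59 at d14 (5 of 16). At d7 their median was 0.14, with Ccn1 higher and Btg2 lower. Fosl2 and Junb were higher with Egr1 at d1, d4 and d14. Proliferation genes had medians of 0.33, 0.12, 0.00 and 1.07, with a mean of -0.03 at d7, and the d14 value was 0.40 at Leiden resolution 1.2 and 0.45 with joint clustering. The members higher were 5 of 17 at d1 including Ube2c (3.47-fold), 1 of 35 at d4 (Tyms), 3 of 33 at d7 (Ccnb2, Cenpf and Nusap1) and 4 of 13 at d14 (Cdk1, Ube2c, Rrm2 and Mcm6). Mural genes had medians of 0.43, 1.05, 0.47 and 1.01. The contractile genes Tagln and Cnn1 were 22.3-fold and 11.0-fold higher at d4, while the channel subunit gene Abcc9 was lower at d1, d4 and d7 (0.440, 0.329 and 0.428 times the rest). Endothelial genes had medians of 0.10, -0.51, -0.42 and 0.01. Kdr and Fabp4 were lower at d4 (0.391 and 0.378 times the rest), and Fabp4, Emcn and Flt1 at d7 (0.483, 0.441 and 0.456), while Aplnr was higher at d1, Vwf at d4, d7 and d14 (2.64-fold, 2.32-fold and 2.98-fold) and Cldn5 at d14.

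Imprinted growth genes had region medians of -0.33, 0.03, 1.36 and 0.58. At d7, where the region held skeletal muscle genes, H19 was 4.37-fold, Dlk1 7.92-fold and Meg3 6.05-fold higher, while Dlk1 was at 0.140 times the rest at d4. Interferon response genes had medians of 0.10, 0.94, 0.55 and 0.59, the d1 value from 3 members and from -0.23 at Leiden resolution 1.2 to 1.22 with joint clustering, and Ifi27l2a was higher in all 4 sections (7.56-fold, 11.2-fold, 3.46-fold and 5.73-fold). Agrin and Yap genes had medians of 0.08, 0.35, 0.55 and 0.25, with Axl higher in all 4 (2.09-fold, 3.63-fold, 2.38-fold and 2.19-fold). Hypoxia genes had medians of 0.20, 0.13, -0.06 and 0.35, the d7 value above 0 with CPM over all genes. The prolyl hydroxylase gene P4ha1 was 5.20-fold higher at d1 and 2.54-fold at d4, and Egln3 was lower at d4 and d14 (0.249 and 0.345 times the rest). Glycolysis genes had medians of -0.16, -0.44, -0.65 and -0.24, with Slc16a3 higher at d1 (2.87-fold) and d4 (7.12-fold) and the muscle phosphofructokinase gene Pfkm lower at d1, d4 and d7. Epicardial genes in the region had medians of 0.30, 1.59, 1.18 and 1.62, atrial genes 1.87, 1.28 and 0.24 at d4, d7 and d14, and reference genes 0.24, 0.19, 0.25 and 0.13.

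**Figure D3:**
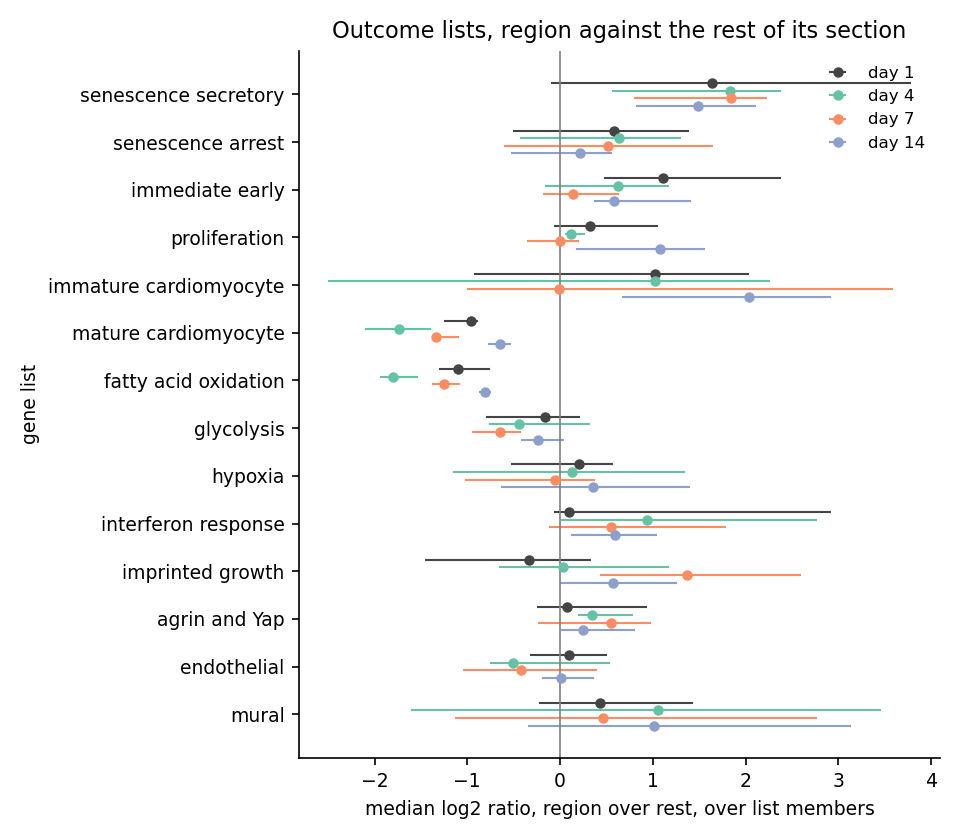
Median log2 ratio of each outcome list's members, injury-list-rich region over the rest of the same section (horizontal axis), for d1, d4, d7 and d14, with order-statistic 95% intervals over members. Senescence secretory genes lay at 1.64, 1.83, 1.84 and 1.48, and mature cardiomyocyte genes at -0.95, -1.74, -1.34 and -0.64.

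After thinning to 2500 UMIs, Spearman's rho across the spots of a section between Egr1 and matrix genes was 0.0777 at d1, 0.166 at d4, 0.0841 at d7 and 0.0995 at d14, at percentiles 95.9, 99.9, 99.7 and 99.4 of matched random lists. In spots outside the region it was 0.0720, 0.110, 0.104 and 0.0416, at percentiles 92.7, 99.7, 99.8 and 88.9, so at d1 and d14 it was not beyond the 95th percentile there. With senescence secretory genes rho was 0.0537, 0.0807, -0.0150 and 0.0736, and with senescence arrest genes 0.0140, 0.0374, -0.0361 and 0.0240. Outside the region these were 0.0423, 0.00538, -0.00622 and 0.0218 for secretory genes and -0.000075, 0.0339, -0.0419 and 0.0501 for arrest genes. Over all spots without thinning, rho at d1 and d4 was 0.127 and 0.223 with secretory genes and 0.184 and 0.268 with matrix genes. With arrest genes at d1 it was -0.0169. At d4, rho was -0.177 with mature cardiomyocyte genes (percentile 0.3), 0.137 with immature cardiomyocyte genes (99.4) and 0.137 with hypoxia genes (99.9). Without thinning these were -0.290, 0.284 and 0.0591, the hypoxia value at percentile 76.6, and outside the region, with thinning, -0.124, 0.0861 and 0.114. The reference genes had rho of 0.0149, 0.0896, 0.0543 and 0.101, with percentiles up to 99.8, so values up to 0.101 were also reached by a list fixed as a reference.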

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

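2 genes of the outcome lists were past the rule of size (at least 2-fold, counting interval excluding 1) in opposite directions in the regions of different sections. The difference between sections was not tested, since each section stood alone. Tnni1, the slow skeletal troponin I of fetal heart muscle, had region over rest log2 ratios of -2.50 at d4, -1 at d7 and 2.04 at d14. Over whole sections it had 2242, 1644, 571 and 6.74 CPM in order of time, so the higher ratio at d14 was found where the gene was lowest. Dlk1, an imprinted growth gene, had a ratio of -2.84 at d4 and 2.99 at d7, where the region also held skeletal muscle genes such as Mylpf (148 CPM against 3.08 in the rest).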

How the results depend on the processing

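The alternative of a region without spots holding a skeletal muscle UMI was chosen after seeing the data. No paired analysis was possible because each time point had 1 section. Egr1 kept its direction against d1 at d4 (log2 ratio 1.93 to 2.46 over 7 alternatives), d7 (2.11 to 2.72) and d14 (-0.75 to -0.21), and in the region at d1 (2.27 to 3.15 over 11), d4 (1.14 to 1.195 over 10), d7 (0.03 to 0.64) and d14 (2.05 to 2.35). Its d7 ratio moved beyond its interval once, to 2.72 without the injury-list-rich region, which lowers the d1 level (10.6 CPM outside it, 15.2 in all). The counts of genes moved with the CPM minimum by construction. With no filter beyond 10 UMIs they were 1088 higher and 328 lower at d4, 674 and 582 at d7, and 1140 and 1156 at d14. With a 50 CPM minimum they were 142 and 48, 101 and 93, and 295 and 191. With TMM factors 192 genes were higher at d4, all of them among the 341. These factors (1.15 at d4 and 1.01 at d1) lower every ratio of d4 to d1 alike, so genes little above 2-fold drop out. Why the factors differed was not tested.

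3 correlations with Egr1 across spots reversed. Spearman's coefficient with proliferation genes at d1 was 0.0453 without thinning (-0.107 with it), that with agrin and Yap genes at d4 was 0.0479 without thinning (-0.0845), and that with mature cardiomyocyte genes at d14 was 0.00189 outside the region (-0.0695). The cause was not tested. Among the other values, 49 moved beyond their interval and 1174 did not, and of the main values 184 did not. The matrix median at d4 was 0.74 without the region and 0.43 without the cluster with the largest atrial share. That cluster was the region itself at d4, d7 and d14 but another cluster at d1, so leaving it out of the reference spots gave a value only at d1. In comparisons with d1, leaving it out took region spots from the later section only. At d7, 34 of the 55 region spots held no skeletal muscle UMI. Without the others the hypoxia median in the d7 region was 0.55. Medians near 0 also turned: at d4 those of mature cardiomyocyte (-0.04) and imprinted growth genes (-0.16) to 0.05 and 0.06 without the largest atrial cluster, and in the region those of agrin and Yap and endothelial genes at d1 and proliferation genes at d7 as means over spots, glycolysis at d1 with joint clustering and endothelial at d14 in 4 of 10 alternatives. Depth limited genes with few counts, such as Egr1 in the d1 region (17 UMIs) and at d14 (54 UMIs over the section).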

Other observations

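The tests on Egr1 over time and on the senescence lists in the region were chosen only after the results were seen, as were the 2 clusters described next. The tests on glucocorticoid-responsive genes were written before their values were seen, but for a pattern already noticed, except the test of the second list outside the region, which was added after.

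The d7 section held 2 clusters led by genes induced by interferon gamma. The 48 spots (6.20%, 4.61% to 8.14%) led by the immunity-related GTPase genes Irgm2 and Igtp with Psmb8 were set against 706 spots outside these 2 clusters, which include the injury-list-rich region. Bst2, an interferon-induced antiviral gene that was kept out of the clustering, had 65.1 CPM there against 37.2 in the other spots (1.75-fold, 1.14 to 2.60), and the interferon response list had a median log2 ratio of 0.68 (-0.08 to 2.08) with 1 of 6 members past the rule of size, not Bst2. The 20 spots (2.58%, 1.59% to 3.96%) led by Tgtp1, the class II gene H2-Aa, Iigp1 and the chemokine genes Cxcl9 and Ccl5 had Bst2 5.29-fold higher (3.65 to 7.51) and Ifi27l2a 4.18-fold higher (2.43 to 6.83). Of 9 macrophage genes, 8 were higher in the smaller cluster (median log2 ratio 1.73), and 0 of 12 in the larger (0.38). Against the 651 spots that leave out the region as well, these were 8 of 9 (2.33) and 3 of 11 (0.82). Over whole sections, Igtp had 0.93 (3 UMIs), 5.13, 45.3 and 17.2 CPM in order of time. At d7, 72 and 118 of its 252 UMIs came from these 2 clusters (162 and 595 CPM). In the largest d7 cluster, of 240 spots, it had 11.8 CPM.

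Egr1 was higher in the d4 and d7 sections than in d1 and d14. Without the region the smaller of its d4 and d7 log2 ratios to d1 was 2.46 (1.93 to 3.03), which argues against the region's spots as the source, and between the d4 and d1 sections, both with Xist and without Y-linked UMIs, it was 2.12 (1.69 to 2.58), which argues against sex at d4. Handling at harvest could induce fast immediate early genes together, and at d7 the 10 others measured outside the region had a median of 1.3 (0.75 to 2.83), 6 of them above 1, while Egr1 had 2.72. The d7 median met the bound set for such induction. At d4 the median of 9 was 0.72 (0.09 to 1.11), with Egr1 at 2.46, and lay between the 2 bounds set. In neither section can such induction and a change in the heart be told apart, because both could raise these genes together. Harvest, sex at d7, age and time after injury stay open, and the fast genes were picked after the values of the full list were seen (0.62 at d4 and 1.10 at d7 without Egr1).

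Genes that glucocorticoids induce were higher in the d1 and d14 sections than in d4 and d7, in a first list picked from genes already seen to do so, such as Fkbp5 (71.6, 17.4, 6.29 and 54.4 CPM in order of time) and Klf15 (51.2, 8.89, 14.5 and 65.0), and genes seen not to do so were left out. A second list of such genes had a median log2 difference of 1.21 (0.39 to 1.85), above 0 in 13 of 14 members and at percentile 100 of random lists. In 9 of the 14, such as Tsc22d3 (154, 93.2, 92.3 and 429 CPM), both d1 and d14 lay above both d4 and d7, and in Angptl4, Rhob, Bcl6, Irs2 and Errfi1, which had been seen as a leading gene of a d14 cluster, they did not. Without the region the difference was 2.19 (1.88 to 3.29) in the first list, against 2.34, and 1.15 (0.48 to 1.86) in the second, which argues against the region as the cause, while TMM factors (2.45, 2.003 to 3.51, in the first list) move all genes by 0.11 and decide nothing. A higher glucocorticoid level at d1 and d14 may be an explanation, while surgery the day before, age, time of day and feeding stay open and were not tested.

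In the region, the senescence secretory list had 9 to 11 of 15 to 17 measured members higher in each of the 4 sections. The arrest list had 1 to 4 of 9 to 14 higher, and at d4 its median also lay at percentile 99.2 of matched random lists. Fewer heart muscle cells per spot would raise the genes of all other cell types alike, but the secretory median exceeded the endothelial one by 2.34 at d4, 2.26 at d7 and 1.47 at d14, with intervals over members that did not overlap (at d4 by little, 0.55 against 0.54), and neither list shares a gene with the list that picked the region. At d1 the difference was 1.54 with overlapping intervals. There, 9 of 15 secretory genes against 1 of 14 endothelial ones had counting intervals wholly above 1.42-fold, the upper end for the endothelial median (Fisher's exact p 0.0052, genes taken as independent). The endothelial medians were themselves -0.51 at d4 and -0.42 at d7, each at percentile 0.51 of matched random lists, which widened the difference there. A loss of endothelial cells was not tested. An excess of secretory genes was also likely in advance, because the region was picked by a list holding matrix and macrophage genes. The difference therefore does not decide on fewer heart muscle cells. More fibroblasts and macrophages per spot could raise the secretory genes. The secretory median lay below the macrophage median, the higher of those 2 lists' medians, in each section (secretory minus macrophage -3.01 to -0.0137). More such cells and a secretory change within cells cannot be told apart, because the region was picked by a list holding matrix and macrophage genes.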
